A study of Mus musculus with 8 samples.

How the data were processed

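Chromatin immunoprecipitation followed by sequencing was carried out in EML_C1, a mouse haematopoietic progenitor cell line that depends on stem cell factor, with antibodies against Ezh2, against histone H3 trimethylated at lysine 27 (H3K27me3) and against Runx1. The series holds 8 libraries. Each antibody had 2 replicates, and 2 input libraries served as controls, 1 for Ezh2 and Runx1 together and 1 for H3K27me3. Chromatin for Ezh2 and Runx1 was fixed with DSG and then formaldehyde, per the labels' protocols, while that for H3K27me3 was fixed with formaldehyde alone. The labels do not say that the replicates were separate cultures, so a spread between them may be technical, and no p-value given here measures variation between cultures. The tests over genes and positions treat genes or positions as the units and describe these libraries.

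The submitters' processing notes name Bowtie2 2.2.1, Picard, SAMtools, MACS2 2.0.10 and the mouse genome build mm10. The notes give neither the role nor the parameters of each tool. The deposited files are 6 peak lists, 1 per library with an antibody, so peaks were not pooled over replicates. Ezh2 and Runx1 came as narrow peaks with a summit, and H3K27me3 came as broad peaks without one. The folds and q-values of H3K27me3 are therefore not directly comparable with those of the other antibodies. The same q cutoff in both kinds of list is not an equal strictness. Each deposited list gives for every peak a score, a fold enrichment, a p-value and a q-value. The deposited score is a whole number, 10 times the -log10 p for narrow peaks and 10 times the -log10 q for broad peaks, and it was not used. The fold enrichment is a linear ratio, as the authors' peak caller wrote it, and so is a value of the authors for each peak. The deposited p- and q-values are on the -log10 scale. The weakest peaks of each list have a p between 0.0493 and 0.0499, so the deposited lists hold many weak peaks. Read totals are not given in the sources used here, so the depth of the libraries is unknown. The number of significant peaks also depends on the antibody, the kind of peak and the input, so it does not measure depth. The input libraries were not analysed here.

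Coordinates are those of mm10, counted from 1. Genes came from a table of RefSeq genes on the assembly GRCm38.p6, which has the same chromosome coordinates as mm10, and 21887 protein-coding genes on chromosomes 1 to 19, X and Y were used. The table gives no strand, exon or transcript, so the start of a gene could not be told from its end. The planned promoter windows were therefore replaced by windows of 1 kb either side of each of the 2 ends of a gene. A gene was called for an antibody where the same window held a peak in both replicates, with an overlap of at least 1 bp. Calls of different antibodies need not share a window, so a gene called for several may carry them at different ends. Among genes that lie close together, the same peak can call both. Without a genome sequence, the planned analyses of the RUNX motif, of CpG-rich promoters, of alternative transcript starts and of exons against introns were not run.

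Regions found in both replicates were the merged peaks of both lists, kept where both lists contributed. Overlap of regions by at least 1 bp was compared with 1000 circular rotations of one set along each chromosome. The planned permutation p was one-sided for more overlap, and where overlap was lower the p of the other tail is given. The smallest p that the rotations can give is 0.001, or 0.002 where two-sided. Sharing of called genes was tested with Fisher's exact test, two-sided, with a 95% confidence interval of the log2 odds ratio, and genes are not replicates. The genes lie in order along chromosomes, so lists and pairs of antibodies were also tested with circular shifts along the gene order, a test added after the data were examined. With 2 libraries against 2, an exact permutation test has a smallest two-sided p of 0.333, so numbers of peaks are given as values without a test. An ± gives the SD over the 2 replicates.

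The 16 gene lists, the rule for naming genes, the tests and all alternatives except the added ones were fixed before the data were examined. The lists were Hox genes, non-blood developmental transcription factors, secreted developmental signals, stem and progenitor regulators, T lymphoid genes, B lymphoid genes, myeloid genes, erythroid and megakaryocytic genes, genes of mast cells, basophils and eosinophils, cytokine receptor and RAS signalling genes, Polycomb and chromatin regulators, cell cycle inhibitors and tumour suppressors, ribosomal protein genes, neuronal genes, structural genes of liver, gut and muscle, and olfactory receptors. All but 1 of the listed symbols matched the gene table. Each list was tested against all other protein-coding genes with Fisher's exact test for each of the 3 antibodies, with Benjamini-Hochberg adjustment over the 48 tests. The rule named up to 3 members per list and antibody with the highest mean fold enrichment among called genes, the 10 genes with the highest mean per antibody, the 5 widest H3K27me3 regions and 25 genes set in advance, which made 151 genes, some of which are not reported here. The fold given for a gene is that of the strongest peak touching a window at its ends.

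Alternatives were a q of at most 0.01, a q of at most 1e-05, the 10000 peaks of each list with the lowest p, 50% of a region or window covered, the summit inside the other set, either replicate alone, replicates compared by number, windows of 2.5 kb and regions away from gene ends. Alternatives added after the data were examined were the gene-order shifts, the whole gene span, stricter peaks for the first antibody of a pair with the second as deposited, and overlaps without the sex chromosomes and without peaks of high significance and low fold. The tests were checked on simulated data that kept the real number of genes and the real widths of regions. Apart from planted effects, positions and gene calls were drawn independently, with fewer rotations than in the main tests. The checks therefore do not cover the clustering of real peaks or of neighbouring genes. Among simulated lists of 36 genes with a planted log2 odds ratio of 3, the list test recovered 100 of 100 for each antibody and called 2, 3 and 2 of 100 unchanged lists for Ezh2, H3K27me3 and Runx1. The rotation test of Runx1 with Ezh2 recovered 20 of 20 planted overlaps of 5% and called 2 of 20 unplanted ones. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.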

Results

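The distribution of H3K27me3, the mark set by Polycomb repressive complex 2, and of the binding sites of its catalytic subunit Ezh2 and of the haematopoietic transcription factor Runx1 was examined in EML_C1 cells. Peak lists of 2 replicates per antibody were compared. Ezh2 had 178354 and 159007 peaks in replicates 1 and 2, H3K27me3 had 220455 and 178423, and Runx1 had 64059 and 66153. The peaks covered 57.0 ± 5.02 Mb for Ezh2, 275.8 ± 103 Mb for H3K27me3 and 24.6 ± 0.948 Mb for Runx1 (SD, n = 2). Among the narrow peaks, those of Runx1 stood higher above background than those of Ezh2. Median fold enrichment was 3.36 ± 0.349 for Runx1 and 2.45 ± 0.0709 for Ezh2. A q of at most 0.01 was reached by 64.7 ± 6.63% of Runx1 peaks and 17.1 ± 4.26% of Ezh2 peaks. This share was 3.73 ± 3.39% for H3K27me3, whose replicate 2 had 2384 such peaks against 13508 in replicate 1. Its peaks are broad and have another input, so its share is not directly comparable.

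Replicates of Runx1 shared most of their peaks, as 70.2% of the peaks of replicate 1 and 67.7% of those of replicate 2 touched a peak of the other, against 2.04% and 1.98% by rotation. For Ezh2 the shares were 39.7% and 45.0%, against 4.52% and 5.06%. For H3K27me3 they were 53.2% and 82.5%, against 16.6% and 22.8%. Each share lay above all rotations, at the smallest possible permutation p of 0.001. Across overlapping peaks, which are not independent replicates, the fold enrichment of the replicates had a Spearman correlation of 0.868 for Runx1, 0.418 for H3K27me3 and 0.280 for Ezh2, and the Pearson correlations of log2 fold were 0.91, 0.45 and 0.45. Regions found in both replicates numbered 65316 for Ezh2, 110650 for H3K27me3 and 44026 for Runx1.

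The first comparison asked how far Ezh2 binding and its mark coincided. In the lists as deposited almost all Ezh2 regions lay in marked chromatin, as 58810 of 65316, or 90.04%, touched an H3K27me3 region. Of 4034 genes with Ezh2 at an end, 3575 were also called for H3K27me3, at the same end or the other. Among them were the T lymphoid transcription factor gene Lef1, the Hox genes Hoxb8 and Hoxc9, and the Wnt ligand gene Wnt11. The mark was wider spread than the protein in these lists, as 25.2% of H3K27me3 regions touched an Ezh2 region and 3118 genes carried the mark without Ezh2. With a q of at most 0.01 in both lists this turned. There 170 genes carried the mark without Ezh2 and 1276 carried Ezh2 without the mark. Rotation gave 16.2% of Ezh2 regions in the mark, so the observed share was 5.54 times higher, at the smallest possible permutation p of 0.001. Over genes, the log2 odds ratio was 5.20 (95% confidence interval 5.05 to 5.35), where 1234 shared genes would be found if the calls were independent, and Fisher's exact p was smaller than double precision can hold. With a q of at most 1e-05 for Ezh2 alone, 93.3% of 2112 Ezh2 regions and 917 of 1003 Ezh2 genes had the deposited mark. With both lists made stricter, which left few H3K27me3 peaks, the share was 15.3% of regions (30.6 times rotation) and 492 of 1768 genes at 0.01, and 5.30% (135 times rotation) and 76 of 1003 genes at 1e-05.

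The strongest Ezh2 peak at a gene end lay inside Bmi1, a gene of Polycomb repressive complex 1 on chromosome 2 (18677018 to 18686629), within 1 kb of an end of Commd3. It had an Ezh2 fold enrichment of 83.9 ± 9.17 (SD, n = 2), beside an H3K27me3 fold of 2.86 ± 0.664 at Bmi1 and a Runx1 fold of 8.85 ± 1.26 at both genes. Next came the shared end of Cryzl1 and Itsn1 on chromosome 16 with an Ezh2 fold of 29.5 ± 8.19, the receptor phosphatase gene Ptpru on chromosome 4 with 27.5 ± 5.16 and the receptor kinase gene Tyro3 on chromosome 2 with 24.6 ± 5.95. L3mbtl3, Rabgap1l, Brwd1 and Gkap1 had Ezh2 folds between 22.5 and 24.3, and all carried H3K27me3. H3K27me3 folds, which are those of broad peaks against another input, were lower throughout. The highest at a gene end was 6.03 ± 0.0438 at Eya1 on chromosome 1 (14168953 to 14311035), a developmental regulator, followed by 5.57 ± 1.34 at Hectd2 and 5.40 ± 2.00 at Zswim5. Of the 10 genes with the highest mean, Reps2, Fgd1 and Sowahd lie on the X chromosome, with H3K27me3 folds of 5.09 ± 1.81, 4.98 ± 0.756 and 4.87 ± 1.48.

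The widest H3K27me3 region found in both replicates spanned 96502 bp on chromosome 15 (78623920 to 78720421), covered an end of Elfn2, and held 40 Ezh2 regions and 0 Runx1 regions. An 80380 bp region on chromosome 11 (96241610 to 96321989) covered the genes from Hoxb9 to Hoxb3 and held 32 Ezh2 regions and 1 Runx1 region. The others of the 5 widest lay inside Plekha6 on chromosome 1 (85216 bp), inside Itsn1 on chromosome 16 (76329 bp) and over an end of the imprinted gene Igf2r on chromosome 17 (75490 bp). They held 1, 1 and 3 Runx1 regions. Ezh2 peaks inside H3K27me3 regions were slightly higher than those outside, with median folds of 2.53 against 2.37 in replicate 1 and 2.48 against 2.36 in replicate 2. The log2 ratios of 0.10 and 0.07 lay beyond all rotations, at the smallest possible two-sided permutation p of 0.002. With peaks of a q of at most 1e-05 the ratio was 0.75 and no longer passed the test (permutation p = 0.323).

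The 4 Hox clusters, which pattern the body axis, differed widely in how much of them was covered. Ezh2 peaks covered 85.0 ± 0.427% of HoxC (chromosome 15, 102921131 to 103036856) and 55.9 ± 2.22% of HoxB (chromosome 11, 96194316 to 96368254), but 22.1 ± 5.85% of HoxA (chromosome 6, 52155367 to 52260880) and 15.9 ± 0.75% of HoxD (chromosome 2, 74668225 to 74765142). H3K27me3 peaks followed the same order, with 93.2 ± 3.97%, 83.2 ± 10.6%, 62.8 ± 15.8% and 40.2 ± 13.3% (SD, n = 2). Runx1 peaks covered 0.380 ± 0.00496% on average over the clusters, and none of HoxA. The averages for Ezh2 and H3K27me3 were 44.7 ± 1.72% and 69.8 ± 10.9%, against 3.04% and 13.1% of the chromosomes that hold the clusters. No test was run on these shares. With peaks of a q of at most 1e-05 the average for H3K27me3 was 0.0426%, while that for Ezh2 was 28.3%.

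**Figure D1:**
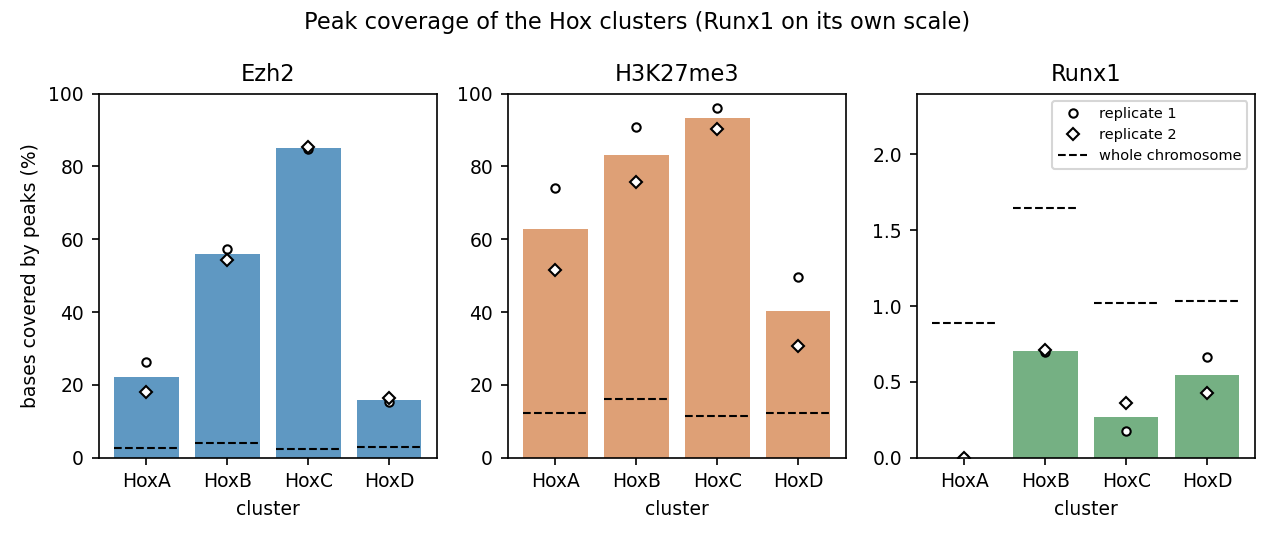
Percent of the bases of each Hox cluster covered by peaks, for the 3 antibodies, with bars for the mean of 2 replicates, circles and diamonds for replicates 1 and 2, and dashed lines for the whole chromosome. Ezh2 and H3K27me3 covered HoxC most, at 85.0% and 93.2%, and Runx1, drawn on its own scale, stayed below its chromosome level in each cluster.

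The second comparison asked where Runx1 bound. In the lists as deposited 22.2% of Runx1 regions were centred within 1 kb of a gene end, against 3.21% by rotation. For Ezh2 the share was 6.72% against 3.32%, and for H3K27me3 it was 4.07% against 3.15%. The highest Runx1 folds at gene ends were 268 ± 12.7 at Dgat2, a triglyceride synthesis gene on chromosome 7 (99153663 to 99182713), 237 ± 34.0 at Plekho2 and 220.0 ± 20.0 at Hddc2. Uba3, Agrn, Syap1, Ccdc9 and Paqr3, and Nln with its neighbour Sgtb, had Runx1 folds between 170.2 and 185. The Runx1 gene itself (chromosome 16, 92601466 to 92826074) carried Runx1 with a fold of 64.0 ± 11.3 and neither Ezh2 nor H3K27me3, and the Ezh2 gene carried Runx1 with a fold of 3.73 ± 0.0227. All 3 shares at gene ends lay above every rotation (permutation p = 0.001, the smallest possible). With peaks of a q of at most 1e-05 the order of the antibodies changed. There the shares were 37.6% of 2112 Ezh2 regions, 32.1% of 165 H3K27me3 regions and 28.8% of 26641 Runx1 regions. At 0.01 Runx1 stayed highest (25.1%), before H3K27me3 (21.1%) and Ezh2 (16.5%). With the 10000 strongest peaks of each list the order as deposited was kept, with 44.4% for Runx1, 28.2% for Ezh2 and 17.3% for H3K27me3. With replicate 2 of Ezh2 alone the log2 fold over rotation fell from 1.02 to 0.55, and with replicate 1 of H3K27me3 alone the share did not pass the test (log2 fold 0.041, permutation p = 0.0879).

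The third comparison asked whether Runx1 met Ezh2 or the mark. Genes with Runx1 at an end mostly lacked both, as 8448 of 9909 carried Runx1 alone, among them Spi1, Mpo, Kit and Flt3. In all, 1145 genes had both Runx1 and Ezh2, where independent calls would give 1826, and 1138 had both Runx1 and H3K27me3, where they would give 3030. Genes with all 3, at the same end or at different ends, numbered 822. They included Bmi1, the T lymphoid regulators Notch1, Hes1 and Tcf7, the B lymphoid repressor gene Bach2, the myeloid and stem cell factor gene Klf4 and the tumour suppressor gene Cdkn2a. Of these, Hes1, Tcf7 and Cdkn2a lost their H3K27me3 call with peaks of a q of at most 0.01, and at 1e-05 none kept it. The log2 odds ratio was -1.28 (95% confidence interval -1.39 to -1.18, Fisher's exact p = 4.58e-130) for Runx1 with Ezh2 and -2.74 (-2.84 to -2.63, Fisher's exact p smaller than double precision can hold) for Runx1 with H3K27me3. Both also lay beyond all shifts along the gene order, at the smallest possible two-sided permutation p of 0.002. With peaks of a q of at most 1e-05 in both lists the first turned to 0.37 (Fisher's exact p = 7.90e-05) and the second weakened to -0.65 (p = 0.0548). With that q for Runx1 alone they were -1.35 and -2.82.

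Over regions, Runx1 was scarce in the mark and slightly frequent at Ezh2. Of 44026 Runx1 regions, 2880 or 6.54% touched H3K27me3, against 15.1% by rotation, and 1837 or 4.17% touched Ezh2, against 2.91%. Runx1 peaks inside H3K27me3 regions were lower than those outside, with median folds of 2.48 against 3.24 in replicate 1 and 3.05 against 3.66 in replicate 2. The log2 folds over rotation were -1.21 and 0.52, each beyond all rotations at the smallest possible permutation p of 0.001, and the log2 ratios of the medians were -0.38 and -0.26 (two-sided permutation p = 0.002, the smallest possible). The depletion in the mark shrank to a log2 fold of -0.42 with replicate 1 alone (13.3% against 17.8%). With stricter peaks in both lists it turned into an excess, on few regions. The log2 fold was 0.73 at a q of at most 0.01, where 248 of 34394 Runx1 regions touched the mark (0.721% against 0.434%). At 1e-05 in both lists it was 1.67, on 28 of 26641 regions (0.105% against 0.0329%). With a q of at most 1e-05 for Runx1 alone it was -1.50. The excess at Ezh2 was 0.18 with replicate 2 alone and 0.19 more than 1 kb from gene ends (2.82% against 2.47%, permutation p = 0.00899), rose to 2.00 and 3.15 with stricter peaks in both lists, and was 0.47 at 1e-05 for Runx1 alone. Ezh2 and Runx1 share an input library, so part of their excess may come from the shared control, and at 1e-05 the ratio of the medians inside and outside the mark no longer passed the test (log2 ratio -0.33, permutation p = 0.282).

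**Figure D2:**
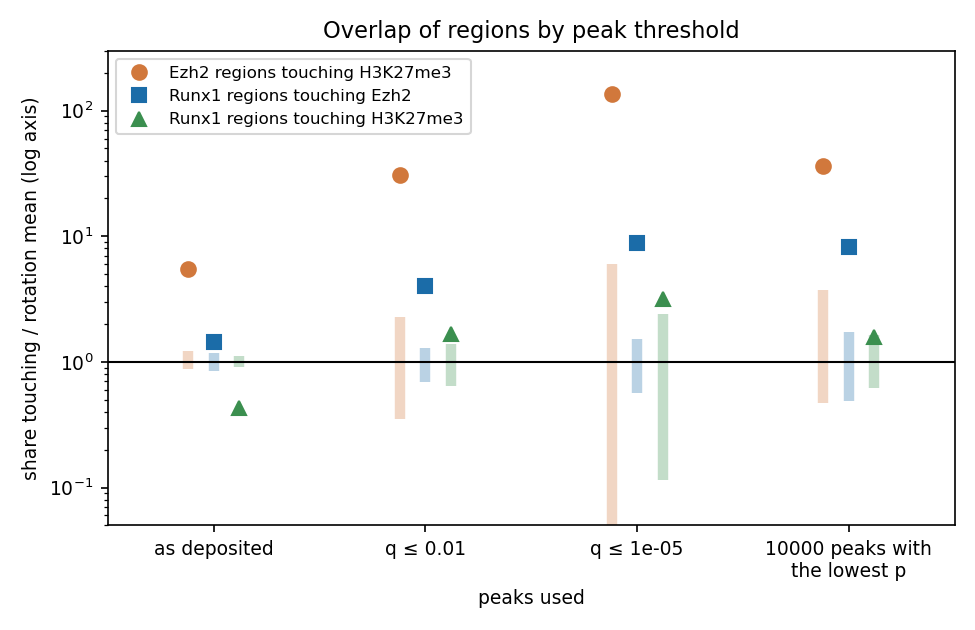
Share of regions touching the other set over the mean of 1000 rotations, on a log axis, for 3 pairs of antibodies and 4 choices of peaks, with shaded bars for the range of the rotations (clipped at the bottom of the axis). Runx1 regions touching H3K27me3 lie below 1 with the lists as deposited, at 0.432-fold, and above it with stricter peaks in both lists, while the other pairs stay above 1. The stricter values of this pair rest on few touching regions, 248 at 0.01, 28 at 1e-05 and 146 with the 10000 strongest peaks.

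The gene lists differed in which antibodies they carried. Of the 16 lists, 7 had Ezh2 more often than other genes and 2 less often, 6 had H3K27me3 more often and 3 less often, and 4 had Runx1 more often and 6 less often. Among all other genes about 18.4% had Ezh2, 30.6% had H3K27me3 and 45.3% had Runx1. Of the named genes, 94 had H3K27me3, of which 47 kept the call with peaks of a q of at most 0.01 and 14 at 1e-05. P-values for the lists are from Fisher's exact test with Benjamini-Hochberg adjustment over the 48 tests.

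**Figure D3:**
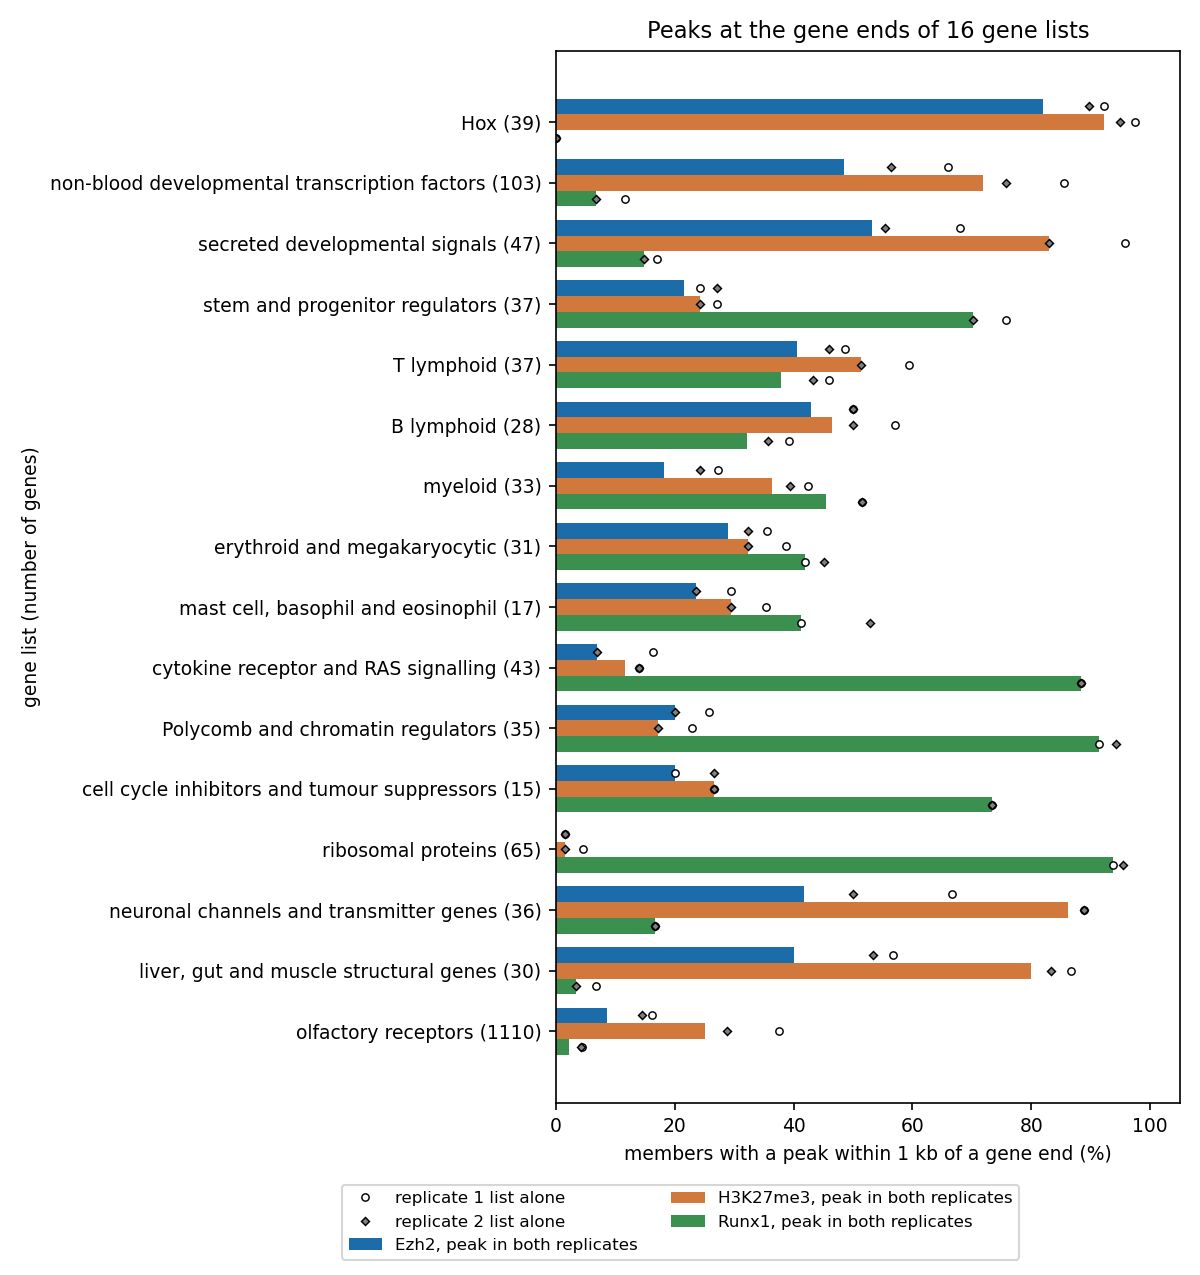
Percent of the genes of each of 16 lists with a peak within 1 kb of a gene end, with bars for peaks in both replicates and points for the list of each replicate alone. Hox genes, other developmental regulators, neuronal genes and structural genes of liver, gut and muscle carry H3K27me3 and little Runx1, while ribosomal protein, Polycomb and signalling genes carry Runx1.

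Developmental genes of other tissues had Ezh2 and its mark more often than other genes and Runx1 less often. Of 39 Hox genes, 32 had Ezh2, 36 had H3K27me3 and 0 had Runx1 (adjusted exact p = 1.07e-16, 6.11e-15 and 4.42e-10). Hox genes are clustered and neighbours share peaks, so these p-values are too small. With shifts along the gene order the adjusted permutation p was 0.00505 for each antibody. Hoxc9 had an Ezh2 fold of 12.8 ± 1.05 and Hoxb8 of 9.40 ± 2.90, while Hoxa9, a gene of haematopoietic stem cells, had Ezh2 at 5.66 ± 0.983 and H3K27me3 at 2.69 ± 0.103. Of 103 non-blood developmental transcription factor genes, 50 had Ezh2, 74 had H3K27me3 and 7 had Runx1 (adjusted exact p = 1.77e-11, 1.05e-16 and 1.05e-16), with Tbx2 at an Ezh2 fold of 12.2 ± 4.34, Pax1 at 5.92 ± 1.06 and Zic2 at an H3K27me3 fold of 3.26 ± 0.129. Of 47 secreted signals, 25 had Ezh2, 39 had H3K27me3 and 7 had Runx1 (adjusted exact p = 2.59e-07, 8.94e-13 and 3.28e-05). Wnt11 had an Ezh2 fold of 13.8 ± 0.139 and Fgf9 of 11.8 ± 1.51, and Wnt10b carried both Ezh2 at 8.10 ± 2.08 and Runx1 at 22.0 ± 0.555. With peaks of a q of at most 1e-05 the H3K27me3 calls of these lists ended, and so did the Ezh2 call of the transcription factors (adjusted exact p = 0.0818).

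Neuronal genes and structural genes of liver, gut and muscle also had Ezh2 and H3K27me3 more often than other genes and Runx1 less often, while olfactory receptor genes had all 3 less often. Of 36 neuronal genes, 15 had Ezh2, 31 had H3K27me3 and 6 had Runx1 (adjusted exact p = 0.00366, 3.36e-11 and 0.00132), such as the glutamate transporter gene Slc17a7 with Ezh2 at 4.82 ± 1.27 and H3K27me3 at 2.98 ± 0.468. Of 30 structural genes of liver, gut and muscle, 12 had Ezh2, 24 had H3K27me3 and 1 had Runx1 (adjusted exact p = 0.0126, 1.04e-07 and 2.04e-06), such as the troponin gene Tnnt2 with Ezh2 at 3.83 ± 2.01. The H3K27me3 calls of both lists and the Ezh2 call of the structural genes (adjusted exact p = 0.780) ended with peaks of a q of at most 0.01, the Ezh2 call of the neuronal genes ended at 1e-05 (adjusted exact p = 1), and their Runx1 call ended over the whole gene span (adjusted exact p = 0.192). Of 1110 olfactory receptor genes, 95 had Ezh2, 279 had H3K27me3 and 24 had Runx1 (adjusted exact p = 1.01e-19, 1.07e-04 and 5.27e-252). The H3K27me3 call did not hold with shifts along the gene order, which keep neighbouring receptors together (adjusted permutation p = 0.116), nor with the list of replicate 1 alone (adjusted exact p = 0.622).

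Stem and progenitor regulators carried Runx1 more often than other genes, with 26 of 37 called (adjusted exact p = 0.00500). Runx1 itself, Zfpm1 with a fold of 139.8 ± 24.7 and Lyl1 with 33.7 ± 9.01 were the highest. Tal1 had a Runx1 fold of 6.35 ± 0.0317, Meis1 of 8.22 ± 1.31, Kit of 4.02 ± 0.116, Cd34 of 3.78 ± 0.756 and Gata2 of 3.49 ± 0.287. In this list 8 genes had Ezh2 and 9 had H3K27me3, which did not differ from other genes (adjusted exact p = 0.825 and 0.620). Bcl11a, Mycn and Erg had both, with Ezh2 folds of 6.32 ± 2.36, 7.07 ± 0.309 and 5.91 ± 2.75. No antibody was called at Lmo2. The Runx1 call ended with peaks of a q of at most 1e-05 (adjusted exact p = 0.0818) and with the 10000 strongest peaks (adjusted exact p = 0.263).

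T lymphoid genes carried Ezh2 and H3K27me3 more often than other genes, with 15 and 19 of 37 called (adjusted exact p = 0.00411 and 0.0190), and 14 had Runx1 (adjusted exact p = 0.564). Of these, 6 had all 3 antibodies. Hes1, a target of Notch signalling, had Ezh2 at 11.3 ± 2.5 and Runx1 at 25.3 ± 0.00437, Notch1 had Ezh2 at 7.45 ± 1.73 and Runx1 at 2.93 ± 0.197, and Tcf7, a T lineage transcription factor gene, had Ezh2 at 5.43 ± 0.188 and Runx1 at 16.1 ± 2.11. Lef1 had Ezh2 at 5.90 ± 2.29 and Gata3 at 5.17 ± 2.14, both with H3K27me3 and without Runx1. Cd3d, a T cell receptor subunit gene, had Runx1 at 60.6 ± 7.14, and Il7r, the interleukin 7 receptor gene, at 7.35 ± 0.608. Rag1 had weak Ezh2 (2.55 ± 1.27) and H3K27me3 (2.52 ± 0.288), and no antibody was called at Bcl11b or Ccr9. Both list calls ended with peaks of a q of at most 0.01, with 6 and 2 genes called (adjusted exact p = 0.203 for Ezh2 and 0.428 for H3K27me3), and passed with the 10000 strongest peaks, with 6 called for each (adjusted exact p = 0.0479 and 0.0429).

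B lymphoid genes carried Ezh2 more often than other genes, with 12 of 28 called (adjusted exact p = 0.00486), while 13 had H3K27me3 and 9 had Runx1 (adjusted exact p = 0.148 and 0.263). Bach2 had Ezh2 at 11.8 ± 3.20 and Runx1 at 10.1 ± 2.45, and Foxo1 had Ezh2 at 5.37 ± 1.3. Cr2, a complement receptor gene, had Ezh2 at 4.85 ± 0.203 and H3K27me3 at 3.08 ± 0.0246. The B lineage transcription factor gene Ebf1 had weak Ezh2 (2.72 ± 0.503) and H3K27me3 (2.38 ± 0.247), and Pax5 had weak H3K27me3 (2.19 ± 0.117). Bank1 and Cd79a had Runx1 at 14.2 ± 0.8 and 8.14 ± 0.629. The H3K27me3 difference passed the test with windows of 2.5 kb (adjusted exact p = 0.0479). The Ezh2 call of the list ended narrowly with peaks of a q of at most 0.01 (adjusted exact p = 0.0506) and further with the 10000 strongest peaks (adjusted exact p = 0.310).

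No antibody differed from other genes in the lists of the remaining blood lineages. Of 33 myeloid genes, 6 had Ezh2, 12 had H3K27me3 and 15 had Runx1 (adjusted exact p = 1, 0.607 and 1). The myeloid regulator gene Spi1 had Runx1 at 33.2 ± 0.0966, Klf4 at 28.4 ± 4.55, Csf2ra at 28.3 ± 5.08, the myeloperoxidase gene Mpo at 17.6 ± 1.29 and Cebpa at 5.92 ± 0.518, while Irf8 had Ezh2 at 9.90 ± 1.11 and H3K27me3 at 2.75 ± 0.185. Csf1r was not called for any antibody. Of 31 erythroid and megakaryocytic genes, 9 had Ezh2, 10 had H3K27me3 and 13 had Runx1 (adjusted exact p = 0.232, 0.935 and 0.935), with Nfe2 at a Runx1 fold of 48.7 ± 0.0737, the integrin gene Itga2b at 18.4 ± 1.11 and the spectrin gene Sptb at an Ezh2 fold of 14.7 ± 1.01. Gata1 was not called. Of 17 genes of mast cells, basophils and eosinophils, 4 had Ezh2, 5 had H3K27me3 and 7 had Runx1 (adjusted exact p = 0.678, 1 and 0.935), with the granzyme gene Gzmb at a Runx1 fold of 23.5 ± 6.39 and the protease gene Cpa3 at 20.5 ± 7.58.

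Genes of signalling, chromatin and protein synthesis had Runx1 more often than other genes. Of 43 cytokine receptor and RAS signalling genes, 38 had Runx1, and 35 of these had it alone (adjusted exact p = 2.88e-08). The adaptor gene Sh2b3, a brake on cytokine signalling, had a Runx1 fold of 119 ± 12.7, Rasa1 of 40.4 ± 3.49, Grb2 of 29.3 ± 2.5 and Flt3 of 4.41 ± 0.751. Of these genes 3 had Ezh2 and 5 had H3K27me3 (adjusted exact p = 0.0799 and 0.0126), and the latter call ended with peaks of a q of at most 0.01 (adjusted exact p = 0.716), while Ezh2 passed the test, as less frequent, with replicate 2 alone (adjusted exact p = 0.0176). Of 35 Polycomb and chromatin regulator genes, 32 had Runx1 (adjusted exact p = 3.99e-08), with Pcgf3 at 97.3 ± 17.1, Rnf2 at 28.8 ± 3.82 and Kmt2a at 28.7 ± 3.45, while 7 had Ezh2 and 6 had H3K27me3 (adjusted exact p = 0.935 and 0.148). With the 10000 strongest peaks Ezh2 was more frequent at them (adjusted exact p = 0.0429). Phf19, an accessory subunit of Polycomb repressive complex 2, carried all 3, with Ezh2 at 6.87 ± 0.758 and Runx1 at 7.27 ± 1.91. Of 65 ribosomal protein genes, 61 had Runx1, 0 had Ezh2 and 1 had H3K27me3 (adjusted exact p = 5.46e-16, 7.49e-06 and 8.74e-09), with Rpl31 at a Runx1 fold of 103 ± 4.08 and Rps23 at 45.5 ± 8.57. The H3K27me3 call of the ribosomal genes ended with peaks of a q of at most 0.01 (adjusted exact p = 0.404). With the 10000 strongest peaks their Runx1 call ended (adjusted exact p = 0.0775), and so did their Ezh2 and H3K27me3 calls (adjusted exact p = 0.0749 and 0.103).

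Of 15 cell cycle inhibitor and tumour suppressor genes, 11 had Runx1, 3 had Ezh2 and 4 had H3K27me3, and none of these passed the test against other genes (adjusted exact p = 0.0609, 0.897 and 1). With windows of 2.5 kb the Runx1 excess passed, with 13 called (adjusted exact p = 0.0137). Cdkn2d had Runx1 at 39.3 ± 5.50 and the retinoblastoma gene Rb1 at 22.4 ± 3.12. The neighbours Cdkn2a and Cdkn2b on chromosome 4 had Ezh2 at 2.63 ± 0.375 and 2.91 ± 0.447 and H3K27me3 at 2.34 ± 0.105 and 3.30 ± 0.585, and Cdkn2a also had Runx1 at 2.51 ± 0.125.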

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

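The tests of the shared input with double fixation and of gene density on the X chromosome were chosen only after the result was seen.

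In genes of mast cells, basophils and eosinophils the small differences from other genes had opposite signs for Ezh2 and for the mark. Ezh2 was found 2.09 and 0.960 percentage points more often than at other genes in replicates 1 and 2, and H3K27me3 was found 3.27 and 3.20 points less often (differences of -3.27 and -3.20), a gap of 4.76 points on average. The list has 17 genes, of which 4 and 5 were called, so each difference is less than the share of 1 gene. Neither passed the test (adjusted exact p = 0.678 and 1), the difference between the antibodies was not tested, and the Ezh2 value was negative with stricter peaks, with windows of 2.5 kb and over the gene span.

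Strict Runx1 regions met strict Ezh2 regions far more often than rotation gave, while the lists as deposited gave a small excess. Gene ends are not the whole cause of the strict excess, although away from them the log2 fold of the deposited lists fell from 0.52 to 0.19, since 1118 Ezh2 regions with a q of at most 1e-05 and more than 1 kb from a gene end still touched Runx1 at 7.38 times the rotation mean (12.3% against 1.67%, highest rotation 2.95%). Regions with a peak of a fold under 3 are also not the whole cause, as the excess was 7.51-fold over the 1934 regions without one. This cutoff cannot exclude repeats of higher fold. An Ezh2 peak on chromosome 3 (5860353 to 5860831 in replicate 1) had folds above it in both replicates. These were 5.33 and 3.91, at a -log10 q of 999.5 and 534.9. A shared input and the double fixation that both proteins had and the mark lacked stay open and cannot be told apart from other causes, since 68.3% of the 142 strict Ezh2 regions outside deposited H3K27me3 touched deposited Runx1, against 29.4% of those inside, but Runx1 was scarce in the mark as a whole, which gives such a difference by itself. No biological explanation was tested.

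Peaks were scarce on the X chromosome in all 6 lists, with 3.69 and 3.04 per Mb for Ezh2 against 74.0 and 66.0 on the autosomes, 17 and 5.40 against 90.5 and 73.9 for H3K27me3, and 5.70 and 6.33 against 26.2 and 27.1 for Runx1. The lower density of genes on X is not the whole cause in the deposited lists, as the ratio of peak densities was at most 0.349 times the ratio of gene densities in each, but with peaks of a q of at most 1e-05 the ratio of H3K27me3 was 0.373 and 0.665, the latter, on 203 peaks in all, close to the gene density ratio of 0.67. A candidate explanation for Runx1 is an X signal lower than that of the autosomes by a factor of 2, since Runx1 peaks of a fold of at least 5 on X against those of at least 10 on autosomes gave a mean of 0.921 times the ratio of gene densities (0.925 and 0.917). For Ezh2 the same value was 1.76 and 2.70, on 23 and 16 X peaks, and 3 of the 10 genes with the highest H3K27me3 fold lie on X, so a lower X signal is not shown for these antibodies. The labels give neither the sex nor the X copy number of the cells, and no biological explanation was tested.

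Replicate 2 of H3K27me3 had fewer significant peaks than replicate 1, 2384 against 13508 at a q of at most 0.01. The values argue against weaker enrichment in replicate 2, since over the regions in both replicates the median ratio of the folds, replicate 2 to replicate 1, was 0.981. Other regions in replicate 2 cannot be told apart from a lower sensitivity, because 86.4% of the significant peaks of replicate 1 touched a peak of replicate 2, which lay between the bounds set for either. Fewer reads in replicate 2 stay open, as the read totals were not used here, and the median -log10 p over the shared regions was 2.2 against 2.56. Both libraries come from one group, so no biological explanation was tested.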

How the results depend on the processing

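The gene-order shifts, the whole gene span, stricter peaks for the first antibody of a pair alone, and overlaps without the sex chromosomes and low-fold repeats were chosen only after the result was seen. The alternatives with CpG-rich promoters, alternative transcript starts and the RUNX motif were not run, for want of a sequence and transcripts. Depth is unknown, and the low number of significant peaks limits H3K27me3 most. Values of overlaps, gene ends and associations are log2 values, and those of lists are percentage points against other genes. Where a value changed, the cause was not tested. Of 189 alternative values that answer a comparison, 152 kept their direction and side of the threshold or stayed within a bound. Of the rest, 28 moved beyond the bound, 5 no longer passed and 4 turned. The bound was a set ratio for counts of peaks and lists, and the spread between replicates for Hox coverage. Of 1830 other values, 1469 kept their direction and side, 295 no longer passed, 11 newly passed and 55 turned.

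The mean number of peaks was 168680 for Ezh2, 199439 for H3K27me3 and 65106 for Runx1. It was 29213, 7946 and 42142.5 at a q of at most 0.01, 4796, 653.5 and 31363.5 at 1e-05, and 10000 each by choice in the last alternative. The overlap of Ezh2 with H3K27me3 stayed an excess in each alternative run, from 2.19 to 7.08, and so did that of Runx1 with Ezh2, from 0.18 to 3.15. That of Runx1 with H3K27me3, at -1.21, turned to 0.73 at a q of at most 0.01, 1.67 at 1e-05 and 0.65 with the 10000 strongest peaks. These turned values rest on 248, 28 and 146 Runx1 regions that touched the mark. With a q of at most 0.01 and 1e-05 for Runx1 alone the value was -1.33 and -1.50. The gene association of Runx1 with Ezh2, at -1.28, turned to 0.37 at 1e-05 and was -0.022 with the 10000 strongest peaks, but -1.35 at 1e-05 for Runx1 alone. That of Runx1 with H3K27me3 was -0.65 at 1e-05. H3K27me3 at gene ends ranged from 0.041 to 0.25 with either replicate left out. The log2 ratio of folds inside and outside the mark was 0.75 for Ezh2 and -0.33 for Runx1 at 1e-05, both without passing the test.

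Mean Hox coverage of Ezh2, H3K27me3 and Runx1 was 36.1%, 34.5% and 0.276% at a q of at most 0.01, 28.3%, 0.0426% and 0.254% at 1e-05, and 31.4%, 40.4% and 0.0414% with the 10000 strongest peaks. At a q of at most 0.01, 4 lists had Ezh2 more often, 3 had H3K27me3 more often and 1 less often. At 1e-05, 2 lists had Ezh2 more often and 1 less often, and 0 had H3K27me3 more or less often by Fisher's exact test with Benjamini-Hochberg adjustment (0 more often and 1 less often at an unadjusted p under 0.05). With the 10000 strongest peaks, 1 list had Ezh2 less often, 1 had H3K27me3 less often and 2 had Runx1 more often.

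Comparing libraries by number, the replicate block, gave 2.33, 0.46 and -0.72 for the overlaps of Ezh2 with H3K27me3, Runx1 with Ezh2 and Runx1 with H3K27me3, 4.89, -1.40 and -2.72 for the gene associations in the same order, and 0.078 and -0.37 for the folds inside the mark. It changed no call among these. The numbers do not pair the libraries, as the differences between replicates correlated over genes at 0.0357, -0.00291 and -0.0111. In the block the same genes enter once per replicate, so its p-values for lists and gene associations are too small. Under it the lists of cytokine receptor and RAS signalling genes (Ezh2), B lymphoid genes (H3K27me3), Polycomb regulators (H3K27me3) and cell cycle inhibitors (Runx1) newly passed the threshold, and the turned lists were myeloid genes for Ezh2 (0.812), Polycomb regulators for Ezh2 (-2.09), cell cycle inhibitors for Ezh2 (-1.61) and erythroid genes for H3K27me3 (-0.101).

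Other list values turned as follows, none of them passing the threshold after the turn. At a q of at most 0.01, Ezh2 turned to 4.05 for myeloid and -8.08 for mast cell genes, H3K27me3 to 5.09 for stem, 2.69 for Polycomb, 10.3 for cell cycle, -0.247 for neuronal and -3.03 for structural genes, and Runx1 to -5.97 for myeloid genes. At 1e-05, Ezh2 turned to 7.55 for myeloid, -4.59 for mast cell and -4.59 for structural genes, Runx1 to -14.8 for myeloid genes, and H3K27me3 to 2.28 for stem genes. There H3K27me3 was called at no member of the Hox (-0.426), developmental factor (-0.427), secreted signal (-0.426), T lymphoid (-0.426), B lymphoid (-0.425), myeloid (-0.426), neuronal (-0.426) and structural (-0.425) lists. With the 10000 strongest peaks, Ezh2 turned to 6.24 for myeloid, -5.89 for mast cell and -5.90 for structural genes, H3K27me3 to 5.21 for stem, 0.104 for Polycomb, 7.73 for cell cycle and -5.62 for structural genes, and Runx1 to -10.2 for myeloid and 1.17 for mast cell genes.

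With either replicate left out, Ezh2 ranged from -0.0495 to 1.67 for myeloid, -2.57 to -1.61 for Polycomb, -3.00 to 4.46 for stem and -7.33 to 4.10 for cell cycle genes, H3K27me3 from -0.355 to 0.153 for erythroid genes, and Runx1 from -6.96 to 4.97 for mast cell genes. Windows of 2.5 kb gave Ezh2 -1.08 for stem and -1.88 for mast cell genes, and Runx1 2.61 for T lymphoid, 12.9 for B lymphoid, 0.163 for erythroid and 7.38 for mast cell genes. With 50% of the window covered, H3K27me3 was 4.47 for cell cycle genes. Over the gene span, Ezh2 was -2.04 for mast cell, -2.89 for Polycomb and -4.79 for cell cycle genes, H3K27me3 -2.87 for myeloid and 1.95 for mast cell genes, and Runx1 10.4 for T lymphoid and 4.40 for B lymphoid genes.

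Newly passing lists outside the block were those in the report and, over the gene span, cytokine receptor and RAS signalling genes for Ezh2 (-19.9), B lymphoid genes for H3K27me3 (25.1) and Polycomb regulators for H3K27me3 (-19.3). Of the genes named by the rule, 70 of 91 kept their Ezh2 call at a q of at most 0.01, 47 of 94 kept their H3K27me3 call and 83 of 85 kept their Runx1 call. At 1e-05 these were 58, 14 and 79.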

Other observations

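The test of gene families and the look at the peaks of highest significance were chosen after the data were examined, so the families and peaks named here were picked after their values were seen.

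Among 101 families of genes with a common symbol stem and at least 20 members, keratins and kallikreins had the mark at each of their genes. Of 53 keratin genes, which encode filaments of epithelial cells, 46 had Ezh2, 53 had H3K27me3 and 2 had Runx1 (Fisher's exact test with Benjamini-Hochberg adjustment over 303 tests, adjusted exact p = 5.22e-25, 7.02e-26 and 6.44e-10). Of 44 collagen genes, 21 had Ezh2, 34 had H3K27me3 and 2 had Runx1 (adjusted exact p = 6.12e-05, 6.23e-09 and 4.51e-08). Of 99 cytochrome P450 genes, 49 had H3K27me3 and 7 had Runx1 (adjusted exact p = 5.53e-04 and 4.62e-15). Keratins and other clustered families share peaks between neighbours, but with shifts along the gene order the unadjusted permutation p of keratins was 0.002, the smallest possible, for Ezh2 and H3K27me3, and 0.00999 for Runx1. Of 26 kallikrein genes, 26 had H3K27me3 and 0 had Runx1, and the lack of Runx1 did not pass with the shifts (permutation p = 0.108). Of 355 vomeronasal receptor genes, 7 had Ezh2, 41 had H3K27me3 and 7 had Runx1, each less often than other genes (adjusted exact p = 1.65e-20, 1.03e-15 and 2.02e-78).

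Several families had Runx1 at most of their genes. All 28 RNA polymerase subunit genes had it and 0 had H3K27me3 (Fisher's exact test, adjusted exact p = 6.23e-09 and 2.70e-04). Runx1 was found at 33 of 35 genes with the stem Vps, 33 of 38 with the stem Cep and 26 of 30 with the stem Snx (adjusted exact p = 3.19e-08, 2.30e-06 and 2.99e-05). It was also found at 48 of 56 genes with the stem Eif, 40 of 49 genes with the stem Mrpl, 26 of 30 Mediator genes and 24 of 26 genes with the stem Cdk (adjusted exact p = 1.05e-08, 3.43e-06, 2.99e-05 and 7.02e-06). Zinc finger genes with the stem Zfp had Runx1 slightly more often, at 209 of 397 (adjusted exact p = 0.00905), which did not pass with shifts along the gene order (permutation p = 0.0579).

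Some of the peaks with the highest significance lay more than 1 kb from any protein-coding gene. Other genes and repeats were not annotated here. On chromosome 2, a peak from 98666686 to 98667182 had a fold of 1.3 in H3K27me3 replicate 1 with a -log10 q of 627, the highest of that list, and a peak at the same place had a fold of 1.32 in Ezh2 replicate 2. In H3K27me3 replicate 2 a peak there was also the most significant, with a fold of 1.25. On chromosome 17, a peak from 39843026 to 39848816 had the highest -log10 q of Ezh2 replicate 1, 1976, with a fold of 4.01. In Ezh2 replicate 2 its fold was 2.46. Such peaks of high significance and low fold may be repeats, which was not tested, so they are not given as binding sites.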
